A study of Mus musculus with 6 samples.

How the data were processed

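Per the labels, 0.3 µg of total RNA from each tibialis anterior sample entered a directional MGI library kit; selection of messenger RNA or removal of ribosomal RNA is not stated. Whether counting used the strand is not given. The submitters' processing notes name FastQC 12.0, Trimmomatic 0.39, STAR 2.7.9a, RSEM 1.3.3 and the mouse build GRCm39 (mm39), without their roles or settings. Groups were taken from the genotype label of each sample: 3 control and 3 knockout libraries.

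The deposited gene table holds log2 values for 14619 genes although its title speaks of raw counts. In each column the values rose in equal steps once 2 was raised to them and 4 was subtracted, so that the deposited log2 value is log2 of a read count divided by 1 factor per library, plus 4. Dividing by the step gave whole reads for 100% of values (tolerance 0.001, largest deviation 6.57e-08). The factors, 1.086, 0.9554 and 0.7996 for control replicates 1, 2 and 3 and 0.9696, 1.138 and 1.127 for knockout replicates 5, 7 and 8, equalled median-of-ratios factors computed from those reads. Genes with few reads were already left out of the file (the lowest value over genes of the highest CPM was 0.503), so fold changes of low genes are understated by the added 4 and genes below that level could not be tested. The same table holds the authors' log2 fold changes and adjusted p-values, of which 9 are missing; the tool behind these deposited p-values is not given.

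The splicing tables are, per the file headers, rMATS junction counts with the p-value and FDR of each event, and CASH junction reads with p-value, FDR and change of inclusion. rMATS columns are headed sample 1 and sample 2 without naming a group. The CASH columns name control and knockout. For exons in both tables with at least 20 exclusion reads in the rMATS cells, the CASH control value equalled the sum of all 3 entries of rMATS sample 1 for 321 of 1441 exons and that of sample 2 for 27 of 1566. The CASH knockout value equalled the sum of the first 2 entries of sample 2 for 484 of 1566 exons (median ratio 1.02), and the sum of all 3 for 2 (median ratio 0.68). Sample 1 was therefore read as control, and the CASH knockout column as the reads of 2 of the 3 knockout libraries, without naming the library left out. In total CASH held 34677717 junction reads for control and 27077335 for knockout, although the knockout libraries held more reads in listed genes. The sign also matched in 8021 of 9857 events shared by both tables. The deposited change of inclusion equalled control minus knockout within 0.01 in 41473 of 41691 CASH events with junction reads in both groups.

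The plan fixed before the data were examined named a count-model test for gene counts, with limma on log values if the table held no counts. Because the file holds log values, that fallback was used. The planned count-model tests were not run on the recovered reads, although this would have been possible. The deposited log2 values were tested with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, prior degrees of freedom 4.63, two-sided, Benjamini-Hochberg adjusted p under 0.05, no covariates), and every adjusted p of a gene is from this fit unless credited otherwise. The median log2 change over all genes was -0.00719, and between -0.00994 and -0.00293 under other scalings. Scaled reads are given as mean ± SD over 3 libraries. The 6 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 10.5 to 42.5), so all 6 libraries were counted. Sex, strain, age and batch are not in the labels used here.

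There were 37 gene lists, fixed before the data were examined, and the 34 with at least 5 measured members were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With the estimated correlation 0 lists passed, and fry, which tests whether a list moves one way on balance, passed 0 (lowest adjusted p = 0.0536). For 3 lists, fast fibre, atrophy, and cholesterol and fatty acid synthesis, the median, the mean and the test differed in sign. Symbols were matched through the gene names and synonyms of a GRCm38 annotation, and for 16 duplicated symbols the row with more reads was kept.

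Named genes followed a rule fixed beforehand. They were Acin1, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean CPM of at least 1 and groups that did not overlap, leaving out models without an assigned name. Up to 4 members per list with the smallest adjusted p were added, and further called members of some lists were named after their values were seen. For rMATS the rule took the 6 largest differences per type with a mean of at least 20 reads per library, plus up to 10 events in the structural, calcium and splicing-factor lists ordered by FDR. For CASH it took the 3 smallest p-values per type. The clause of the rule that asks for groups without overlap was not applied to rMATS events. Mybpc1 and Itga7 in CASH fall outside that rule and are given because rMATS named the same exons, a choice made after their values were seen.

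Some items that the naming rule selects are not reported here. Splicing calls are the authors' own p-values, limited here to rMATS events with FDR under 0.05, an inclusion difference of at least 0.05 and a mean of at least 10 junction reads per library. The columns name no group or sample, and for that case the plan takes the authors' values, so the planned per-library splicing tests were not run. The group order read from the match with CASH served for directions, not for tests per library. Overlaps were tested with Fisher's exact test, directions with exact binomial tests and intron lengths with 100000 permutations (scipy 1.17.1, pandas 2.3.3, numpy 2.4.6, Python 3.11.15). Coordinates are those of the files (GRCm39). Exon overlaps between named genes were read from a GRCm38 annotation by identifier, without its coordinates.

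On simulated reads for these 14619 genes and 6 libraries with 200 changed genes, limma recovered 30% of 50 genes changed 1.5-fold, 80% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold. It called 163 genes, of which 9 (5.52%) were unchanged, and 0 when no gene was changed. Alternatives covered scaling, weighting, filters, the added constant, leaving out each library, list tests, and thresholds on splicing events.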

Results

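RNA was sequenced from the tibialis anterior, a mostly fast-twitch muscle of the shin, of mice that all carried HSA-Cre, a Cre recombinase driven by the human skeletal actin promoter and active in skeletal muscle fibres. The 3 control libraries came from mice with wild-type Acin1 alleles, and the 3 knockout libraries from mice with floxed alleles on both chromosomes. Acin1 encodes acinus, a nuclear RNA-binding protein that takes part in splicing and assembles with RNPS1 and SAP18 into the ASAP complex. The comparison asks what the loss of Acin1 in muscle fibres does to gene expression and to splicing. The control libraries, replicates 1, 2 and 3, held 27190731, 25777196 and 21084522 reads in the 14619 listed genes. The knockout libraries, replicates 5, 7 and 8, held 26968597, 29301125 and 27825425. Mitochondrial genes took 21.4% to 24.1% of these reads. The lowest correlation of log values was 0.985 within the control group and 0.978 within the knockout group, and correlations between the groups ran from 0.966 to 0.979. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries.

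Acin1 (ENSMUSG00000022185, chromosome 14) was lower in every knockout library than in every control library. Its scaled reads, the read count divided by the authors' factor for each library, were 1513, 1559 and 1413 in the control libraries and 1196, 1196 and 1195 in the knockout libraries. The means were 1495 ± 74.3 and 1196 ± 0.775 (SD, n = 3 each). In scaled reads, 80% of the control level was thus left in whole muscle. The log2 change was -0.32 (SE 0.0709, limma adjusted p = 0.0266), and an exact two-sided permutation test of CPM, 57.25 ± 3.43 against 45.96 ± 2.73, gave p = 0.1, the smallest that 3 against 3 libraries allow. The limma call was lost without control replicate 1 (adjusted p = 0.0831), control replicate 2 (0.0973), control replicate 3 (0.0587) or knockout replicate 7 (0.082), at log2 changes between -0.36 and -0.29. Gene-level reads come from all exons and from all cells of the muscle, those without Cre included. The authors' deposited table of CASH, a splicing caller, listed Acin1 exon 27 (GRCm39, chromosome 14, 54880745 to 54881281) with 298 reads for inclusion and 0 for exclusion in the control libraries. That count of 0 allows up to 1.01% exclusion. In the knockout column the same table gave 33 and 116 reads, an inclusion of 22.1% (95% exact binomial interval 15.8 to 29.7), with a deposited FDR of 0.193.

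In the knockout muscle 10 of 25 neonatal and regenerating fibre genes rose, and 6 of 17 endothelial, 5 of 15 smooth muscle and 4 of 14 Schwann cell markers fell. These lists passed camera with a preset correlation and not with an estimated correlation (adjusted p = 0.775 for each). Igfn1, a sarcomeric protein of the immunoglobulin family, went from 1850 ± 1010 to 17480 ± 8195 scaled reads (SD, n = 3 each, log2 change 3.35, adjusted p = 0.00622). H2-K1, a class I histocompatibility heavy chain, went from 1275 ± 1.02 to 793 ± 77.5 (-0.69, adjusted p = 0.00432). Across all 14619 genes, limma called 1645 at an adjusted p under 0.05, 839 higher and 806 lower, with a median absolute log2 change of 0.575, and 357 of them changed at least 2-fold (185 higher, 172 lower). At an unadjusted p under 0.05 there were 4278. The groups did not overlap for 5168 genes, 35.4%, where chance gives 10%. The count fell to 477 without control replicate 1, 488 without control replicate 2, 511 without control replicate 3 and 698 without knockout replicate 7. The authors' deposited table called 1776 genes, 909 higher and 867 lower, of which 1490 were among the 1645 and had the same direction.

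In log2 values with 4 added to the scaled reads, the largest of the 12 rises was that of Gdpd3, a lysophospholipase D, at 14.9 ± 3.12 scaled reads in the control and 398 ± 85.6 in the knockout libraries (log2 change 4.41, SE 0.208, adjusted p = 6.95e-05). The authors' deposited table gave larger log2 changes for Mymk (4.82) and Sln (4.76) than for Gdpd3 (4.73). Sln, or sarcolipin, a small inhibitor of the sarcoplasmic reticulum calcium pump, went from 22.9 ± 2.89 to 622 ± 706 (3.85, adjusted p = 0.015). Its knockout libraries spread from 121.7 in replicate 5 and 314.5 in replicate 7 to 1429 in replicate 8. Padi1, a peptidylarginine deiminase, rose by a log2 change of 3.42, and Birc5, or survivin, a mitotic regulator and apoptosis inhibitor, by 3.40. Mymk, which encodes the myoblast fusion protein myomaker, rose by 3.19, from 3.07 ± 1.35 to 87.5 ± 92.6. Prrxl1, a homeobox gene of sensory neurons, rose by 3.14, and Chrna9, an acetylcholine receptor subunit, by 2.69. Myh8 and Myh3, the perinatal and embryonic myosin heavy chains, rose by 2.85 and 2.41. Ces2c, a carboxylesterase, rose by 2.61 and Sntg2, a syntrophin, by 2.24. Each of these values is over 3 libraries per group. Calls were lost for Sln without control replicate 1, 2 or 3 (adjusted p = 0.0598, 0.053 and 0.0599), and for Mymk without these or knockout replicate 7 (0.0641, 0.0655, 0.0676 and 0.0528). Chrna9 was not called without control replicate 1, 2 or 3 (0.081, 0.105 and 0.101), Myh8 without control replicate 2 or 3 (0.0511 and 0.0556), and Myh3 without control replicate 1 or 2 (0.0582 and 0.0573). With limma-voom on the recovered reads the calls of Sln, Mymk, Chrna9, Myh8 and Myh3 were lost (adjusted p = 0.166, 0.129, 0.142, 0.0826 and 0.0625). Robust limma lost Sln and Chrna9 (0.078 and 0.0554), and limma without the trend lost Sln, Mymk, Chrna9 and Myh3 (0.0552, 0.0583, 0.0853 and 0.0537).

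Among the 12 largest falls, Rsc1a1 had 252 reads in the control libraries, 88.3 ± 21.7 scaled reads (SD, n = 3), and 0 reads in all 3 knockout libraries. Set against a floor of 3 counts over the group, it was at least 95.2-fold lower (limma adjusted p = 0.000196). Myl3, the slow and ventricular essential myosin light chain, fell from 1707 ± 669 to 344 ± 196 scaled reads (log2 change -2.42, SE 0.435, adjusted p = 0.0138). Slc15a5, a predicted peptide transporter, changed by -2.40, Tecta, or alpha-tectorin of the inner ear matrix, by -2.33, and Slc39a2, a zinc importer, by -2.25. Rmi2, a subunit of the BLM helicase complex, changed by -2.10 and Golm1, a Golgi membrane protein, by -2.10. Efcab6 and Lrp2bp both changed by -1.83. Amd2 (-2.02) and Amd-ps3 (-1.85), near copies of S-adenosylmethionine decarboxylase, are uncertain, since reads shared with a paralog can be split by the counting. The antisense RNA Cpeb1os1 changed by -1.98 and shared no exon bases with another annotated gene. Of Acin1 and these 24 genes, 10 share exon bases with another annotated gene, on the same strand for Rsc1a1 (with Ddi2) and Slc39a2 (with Mettl17). On the opposite strand this holds for Acin1, Gdpd3, Golm1, Lrp2bp, Myl3, Padi1, Rmi2 and Tecta. Reads in shared bases can be split by the counting, on opposite strands if it did not use the strand, which is not given. Values of these 10 genes are therefore uncertain, the 95.2-fold of Rsc1a1 included. Slc39a2 lies 2.75 Mb from Acin1 on chromosome 14. Calls were lost for Myl3 without control replicate 3 (adjusted p = 0.0559) and for Efcab6 without control replicate 1, 2 or 3 (0.0683, 0.0695 and 0.0771). Without control replicate 1, 2 or 3 or knockout replicate 7 they were lost for Slc15a5 (0.0831, 0.0836, 0.0606 and 0.0732) and for Amd-ps3 (0.103, 0.139, 0.123 and 0.0837). Robust limma lost Myl3, Slc15a5 and Amd-ps3 (adjusted p = 0.0757, 0.0617 and 0.0899). Limma without the trend lost these (0.0534, 0.0706 and 0.108) and Efcab6 (0.0648), and Amd-ps3 was also lost with 1 or 0.1 added in place of 4 (0.0545 and 0.0585).

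**Figure D1:**
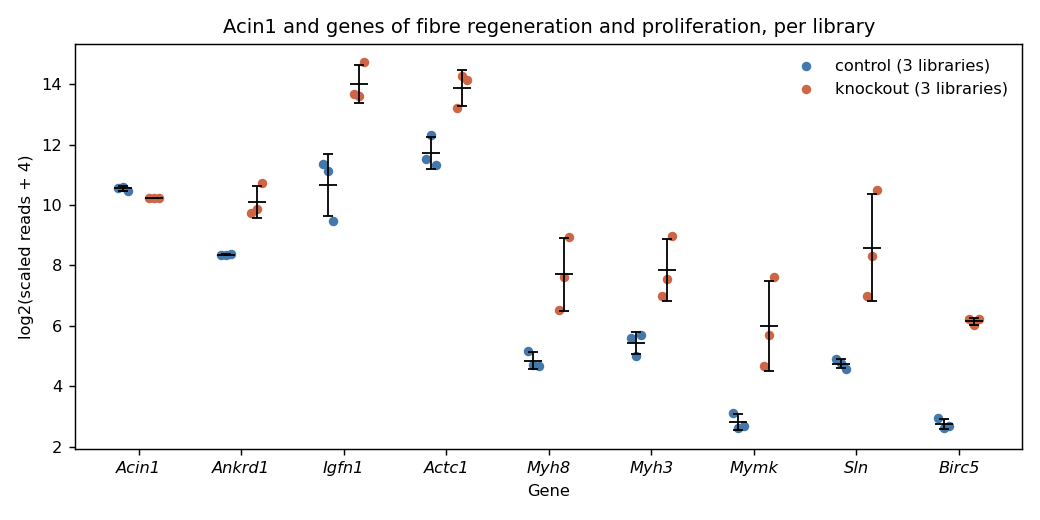
Expression of Acin1 and of 8 genes that rose, as log2 of scaled reads plus 4 (vertical axis), for each control (blue) and knockout (red) library, with the group mean and SD (n = 3) in black. Every knockout library lies below the control libraries for Acin1 and above them for the other genes, and for Sln the knockout libraries spread from 121.7 to 1429 scaled reads.

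Of 25 genes of neonatal and regenerating fibres, 10 rose, 0 fell and 15 did not pass, and 12 rose when adjusted over the list alone. The list's median log2 change was 0.85 (camera adjusted p = 9.24e-07, adjusted p = 0.775 with an estimated correlation), and 0.54 without knockout replicate 8. Besides Igfn1, Myh8, Myh3 and Mymk these were Ankrd1, Actc1, Myl4, Csrp3, the imprinted RNA H19 and Myl6b. Ankrd1, a titin-associated repeat protein, went from 322 ± 4.07 to 1154 ± 453 scaled reads (SD, n = 3 each, log2 change 1.76, limma adjusted p = 0.00432), and Actc1, cardiac alpha-actin, from 3546 ± 1382 to 15700 ± 5545 (2.14, adjusted p = 0.00731). The list's mean log2 value lay above the control mean by 0.68 in knockout replicate 5, 1.01 in replicate 7 and 1.89 in replicate 8. Without control replicate 1, 2 or 3, 4, 3 and 7 members were called, and 13, 6 and 9 without knockout replicate 5, 7 or 8. Of 21 denervation and neuromuscular junction genes, 2 rose (3 over the list alone), Sln and Chrnb1, a receptor subunit of the neuromuscular junction (0.36). Scaling by library size lost Chrnb1 (adjusted p = 0.0777). The list passed at camera adjusted p = 0.021 (adjusted p = 0.826 with an estimated correlation), and not without knockout replicate 8 (0.14). Its called members numbered 0 without control replicate 1, 2 or 3, 7 without knockout replicate 5 and 1 without replicate 7 or 8. The fetal receptor subunit Chrng stood at 2.71 ± 2.53 and 50.8 ± 61.3 scaled reads and was not called (adjusted p = 0.0556). Macrophage markers, measured in the same libraries, had a mean log2 value of 0.95 above the control mean in knockout replicate 8 against 0.04 in replicate 7 and -0.46 in replicate 5.

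Of 16 slow fibre genes, 2 rose (Sln, and the slow troponin I gene Tnni1 with 2.14), 1 fell (Myl3) and 13 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.0688). The list did pass without control replicate 3 (0.0454) or knockout replicate 5 (0.000935), where 0 and 9 members rose. None rose without control replicate 1 or 2, and 1 rose without knockout replicate 7. Myh7, the slow myosin heavy chain, was at 77.1 ± 60.9 and 317 ± 285 scaled reads (SD, n = 3 each, adjusted p = 0.0961). None of 18 fast fibre genes was called (limma), over all genes or over the list alone; Myh2, the type IIA myosin heavy chain, stood at 17990 ± 7804 and 37240 ± 13020 (unadjusted p = 0.0125, adjusted p = 0.0767). Without knockout replicate 5, Myh2 was called (0.0254). Of 29 sarcomere and Z-disc genes, 4 rose in both adjustments: Pdlim7 (0.46), Mybph (1.26), Csrp3 (1.91) and the small heat shock protein Cryab (0.77). The list did not pass (camera adjusted p = 0.248), except without control replicate 3 (0.0127), and 2 members rose without control replicate 1 or 2 or knockout replicate 7. Robust limma lost Tnni1, Mybph and Csrp3 (adjusted p = 0.0756, 0.052 and 0.103), and limma-voom lost Tnni1 (0.112).

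The dystrophin complex and laminin list held 19 genes, of which 3 fell and 1 rose (3 and 2 over the list alone, camera adjusted p = 0.21). Sgcb, the beta sarcoglycan of the fibre membrane, changed from 2489 ± 147 to 1519 ± 9.81 scaled reads (SD, n = 3 each, log2 change -0.71, SE 0.0714, limma adjusted p = 0.00215). Delta-sarcoglycan, Sgcd, rose from 67 ± 4.84 to 132 ± 26.6 (0.91), and Itgb1, the beta-1 integrin, changed by -0.34. Sgcd was not called without control replicate 1, 2 or 3 (adjusted p = 0.0691, 0.0632 and 0.0533), nor Itgb1 without control replicate 2 or 3 or knockout replicate 7 (0.0692, 0.0766 and 0.056). Of 26 genes of calcium handling and excitation-contraction coupling, 3 fell in both adjustments: Camk2a (-0.48), the reticulum protein Srl (-0.39) and the triad protein Jph1 (-0.38, adjusted p = 0.0498). The list did not pass (camera adjusted p = 0.3). None of its members fell without control replicate 1, 2 or 3, and 1 fell without knockout replicate 7 or 8. Jph1 was also lost with limma-voom (0.056) and with 1 or 0.1 added in place of 4 (0.0507 and 0.0522).

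The list of 24 p53 target and apoptosis genes had 5 members that rose in both adjustments and 19 that did not pass (camera adjusted p = 0.00825, adjusted p = 0.783 with an estimated correlation). Aen, a p53-induced nuclease, rose from 1211 ± 77.8 to 1709 ± 52.5 scaled reads (SD, n = 3 each, log2 change 0.50, limma adjusted p = 0.00843). Eda2r, the ectodysplasin A2 receptor, rose by 1.07 and Cdkn1a, the cell cycle inhibitor p21, by 1.53. Zmat3 (0.43) and Bax (0.54) were the other members called. The list was lost without knockout replicate 8 (0.0544), and 2 members were called without control replicate 1, 2 or 3 and 3 without knockout replicate 7 or 8. Of 22 cell cycle genes, 1 rose, Birc5, from 2.76 ± 0.827 to 67.3 ± 5.8 scaled reads (3 over the list alone, camera adjusted p = 0.0132, adjusted p = 0.775 with an estimated correlation). Without knockout replicate 8 the list did not pass (0.0829), and 3 members rose without knockout replicate 5. Of 27 unfolded protein response and heat shock genes, 3 rose, Hsp90aa1 (0.54), Hspa1a (1.40) and Bag3 (0.32), and 6 over the list alone. Camera gave an adjusted p of 0.021 (adjusted p = 0.826 with an estimated correlation), and 0.0531 and 0.134 without control replicate 1 or knockout replicate 8. None rose without control replicate 1 or 2, and 1 without control replicate 3. Robust limma lost Cdkn1a and Hspa1a (adjusted p = 0.105 and 0.052), limma-voom lost Hspa1a (0.0723), and scaling by library size lost Zmat3 (0.0524). Hspa1a and its near copy Hspa1b share sequence, so their separate values are uncertain.

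Inflammation and interferon genes numbered 22, of which 6 fell, 0 rose and 16 did not pass (7 fell over the list alone; camera adjusted p = 9.5e-05, adjusted p = 0.775 with an estimated correlation). Complement C3 changed from 279 ± 60 to 93.1 ± 19.3 scaled reads (SD, n = 3 each, log2 change -1.54, limma adjusted p = 0.00493). H2-K1 (-0.69), H2-D1 (-0.60) and B2m (-0.40) encode the chains of class I histocompatibility molecules, and Ifi27 (-0.39) an interferon-induced protein. Histocompatibility genes have near copies in the genome, so their counts are uncertain. The list passed without each library in turn. Without control replicate 1 or 2, 3 of its members fell, and without knockout replicate 7, 4.

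Markers of several other cell types were lower. Of 17 endothelial markers 6 fell, Ptprb, Tie1, Tek, Pecam1, Flt1 and Aqp1, and 11 did not pass (13 fell over the list alone, camera adjusted p = 1.22e-05). Pecam1 went from 1760 ± 64.9 to 1361 ± 137 scaled reads (SD, n = 3 each, log2 change -0.37, limma adjusted p = 0.0311). Of 15 smooth muscle and pericyte markers 5 fell (10 fell and 1 rose over the list alone, camera adjusted p = 0.00122), among them Rgs5 of pericytes (-0.49), Tagln (-0.45), Mylk (-0.48) and the Notch receptor Notch3 (-0.53). Of 14 Schwann cell and nerve markers 4 fell (6 over the list alone, camera adjusted p = 0.000778). Prx (-0.66), Cdh19 and Pmp22 (-0.44) were among them. For each of these 3 lists the adjusted p was 0.775 with an estimated correlation. The lists passed without each library, but without control replicate 1 or 3 no member of them fell. Without control replicate 2, 1 endothelial, 1 smooth muscle and 2 Schwann markers fell. Without knockout replicate 5, 3, 2 and 2 fell, without replicate 8, 2 endothelial and 3 smooth muscle markers, and without replicate 7, 1 Schwann marker. Scaling by library size lost Pecam1 and Pmp22 (adjusted p = 0.0631 and 0.081). None of 17 fibro-adipogenic progenitor markers was called by limma in either adjustment, the smallest unadjusted p being 0.00699 for Ly6a. Their list still passed (median -0.29, camera adjusted p = 0.021, adjusted p = 0.883 with an estimated correlation), but not without control replicate 1 (median -0.175, adjusted p = 0.211) or knockout replicate 5 (median -0.08, adjusted p = 0.52). The 8 erythrocyte markers had a median of -1.25 with 0 called by limma and 5 over the list alone (camera adjusted p = 0.0173, adjusted p = 0.826 with an estimated correlation, 0.0743 without knockout replicate 8), and 3 fell without control replicate 3 and 1 without knockout replicate 5. Their median was -0.75 without control replicate 2, whose mean log2 value for these markers lay 1.03 above the control mean, against -0.225 and -0.807 in control replicates 1 and 3.

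Among splicing factors, changes went both ways. Of 28 core spliceosome genes 4 rose in both adjustments and 24 did not pass (camera adjusted p = 0.0387, adjusted p = 0.775 with an estimated correlation). Snrnp70, a protein of the U1 particle, rose from 2372 ± 153 to 3378 ± 91.7 scaled reads (SD, n = 3 each, log2 change 0.51, limma adjusted p = 0.00649), with Snrpa (0.45), Snrpd3 (0.30) and Snrpe (0.38). The list was lost without control replicate 1 (0.0777), control replicate 3 (0.0786), knockout replicate 5 (0.07) or knockout replicate 8 (0.0695). Without any 1 control library 1 member rose, and 2 without knockout replicate 5 or 7. Scaling by library size lost Snrpe (0.0532) and, among the hnRNP genes, Hnrnpc (0.0542). Of 25 SR proteins and their kinases, Clk3 (0.43), Luc7l3 (0.31) and Srsf11 (0.34) rose and Clk4 (-0.39), Srsf5 (-0.35) and Clk1 (-0.32) fell, with 5 higher and 5 lower over the list alone (camera adjusted p = 0.987). None of them was called without control replicate 1, 2 or 3 or knockout replicate 7, and 2 rose and 2 fell without knockout replicate 5. Of 13 genes of the ASAP and PSAP complexes and the exon junction complex, Pnn, or pinin, a partner of RNPS1, rose from 652 ± 23.1 to 802 ± 10.9 (0.30, adjusted p = 0.0376; camera adjusted p = 0.846). Over the list alone 1 rose and 1 fell. Pnn was not called when any 1 library was left out (adjusted p from 0.0592 to 0.111). Of 24 hnRNP and muscle splicing regulators 1 fell in both adjustments, Hnrnpc (-0.37), which lies 2.57 Mb from Acin1, and the list did not pass (0.196). Hnrnpc was not called without control replicate 1, 2 or 3 (0.0611, 0.101 and 0.0988) or knockout replicate 5 or 7 (0.0582 and 0.0887).

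**Figure D2:**
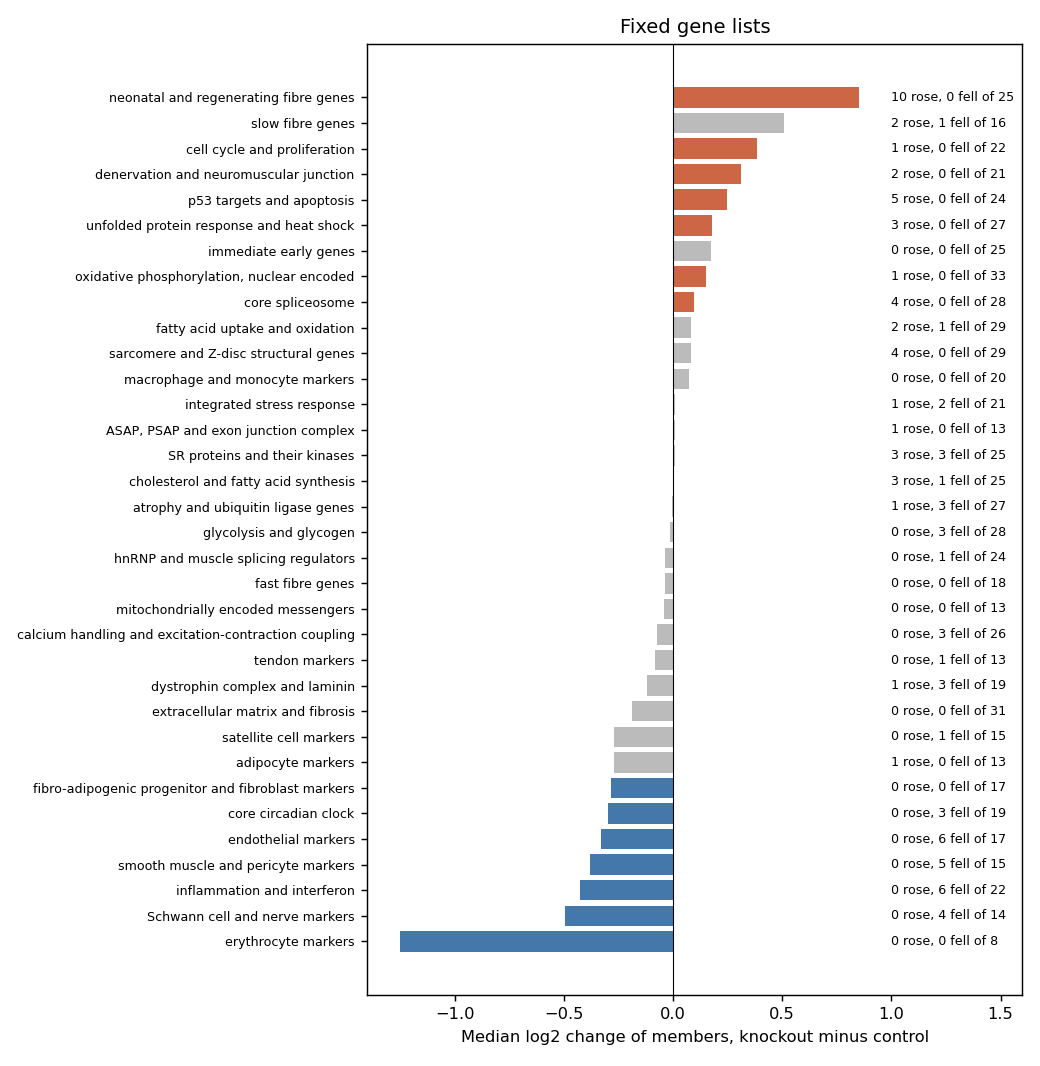
Median log2 change, knockout minus control, of the measured members of each of 34 gene lists (horizontal bars), with the number of members that rose and fell at an adjusted p under 0.05. Red and blue bars are the 7 higher and 7 lower lists past camera with a preset correlation, none of which passed with an estimated correlation (lowest adjusted p = 0.775), and grey bars are lists that did not pass. The neonatal and regenerating fibre list stands highest with 0.85 and the erythrocyte list lowest with -1.25.

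In the authors' deposited table of rMATS, which compares reads across splice junctions, skipped exons made up most of the events tested and most of those called. Of the skipped exons tested 2.78% were called, against 2.46% to 3.71% in the other types. Among called events, inclusion was more often higher in the control muscle. Of 22946 events with a mean of at least 10 junction reads per library, the authors' deposited table had 665 in 464 genes at an FDR under 0.05 and an inclusion difference of at least 0.05. Of 15528 skipped exons 431 were called in 321 genes, 289 with higher inclusion in the control and 142 in the knockout libraries, per the authors' deposited table. An exact two-sided binomial test of that split gave p = 1.24e-12, with 32.9% higher in the knockout (95% exact binomial interval 28.5 to 37.6), events of one gene not being independent. All events come from the same 6 libraries, so binomial p-values of this kind do not measure the spread between libraries. The authors' deposited table gave 37 of 1246 alternative 5' splice sites (19 higher in control, 18 in knockout) and 53 of 2154 alternative 3' splice sites (31 and 22). It also gave 69 of 1861 mutually exclusive exon pairs (37 and 32) and 75 of 2157 retained introns (30 and 45), again from the authors' deposited table. These 4 splits gave exact binomial p-values of 1, 0.272, 0.63 and 0.105. The columns do not name the groups: which is which was read from a match with the CASH table, in which 306 of 312 called events shared by both had the same sign.

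**Figure D3:**
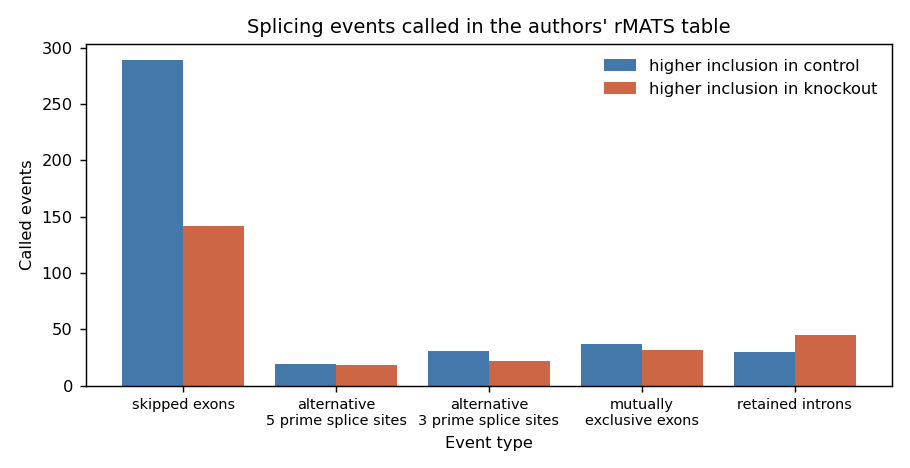
Number of events called in the authors' rMATS table (vertical axis) by event type, with inclusion higher in the control (blue) or the knockout (red) libraries. Skipped exons show 289 and 142 events, and retained introns 30 and 45.

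Exons of structural muscle genes were among the events. In Mybpc1, slow myosin-binding protein C, the authors' deposited table gave an inclusion difference of 25.8 percentage points, higher in the knockout, for an exon of 59 bp (GRCm39, chromosome 10, 88357139 to 88357197, FDR 0). The same exon joined to other flanking exons was 8.6 points higher in the control (FDR 1.74e-08) in the authors' deposited table. A titin exon of 303 bp (Ttn, chromosome 2, 76536014 to 76536316) was 13 points higher in the knockout in the authors' deposited table (FDR 6.92e-11). In Neb, the nebulin gene, an exon of 105 bp was 14.6 points higher in the control in the authors' deposited table (chromosome 2, 52075283 to 52075387). For Itga7, the laminin receptor integrin alpha-7, the authors' deposited table gave an exon of 113 bp that was 23.6 points higher in the control (chromosome 10, 128792480 to 128792592, FDR 1.32e-10). In Bin1, which shapes the transverse tubules, an exon of 72 bp was 15.3 points higher in the knockout (chromosome 18, 32564724 to 32564795, FDR 2.45e-09), per the authors' deposited table. Acin1 and all genes of the structural, calcium and splicing-factor lists together held 1006 tested events. Of these 71, in 26 genes, were called, against 665 of 22946 over all genes, per the authors' deposited table. None of the called events was in Acin1, and the tested Acin1 events did not include the exon 27 listed by CASH.

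The largest differences per type lay elsewhere. For skipped exons they included 62.7 and 60 points, both higher in the control, at 2 exons of the phosphatase gene Dusp13 (chromosome 14, 21794816 to 21795010 and 21796378 to 21796585) in the authors' deposited table. The muscle RNA Nctc1 followed with 48.4 points, higher in the control, over 243 reads per library, and the slow troponin T gene Tnnt1 with 47.9 points, higher in the knockout, in the authors' deposited table. Among 3' splice sites, Mast2 (51.9 points) and Popdc3 (40.9 points), a cyclic AMP binding membrane protein of striated muscle, were higher in the control in the authors' deposited table. Among 5' splice sites, the authors' deposited table gave Pard3 35.2 points, higher in the control, and Scaf11, an SR-related splicing factor, 26 points, higher in the knockout. Introns of Slc25a15, the mitochondrial ornithine carrier, Mief2, a mitochondrial fission adaptor, and Thoc1, of the THO export complex, were retained more in the knockout by 40.5, 40.2 and 37 points, per the authors' deposited table. An intron of Htra2, a mitochondrial protease, was retained more in the control by 33.8 points in the authors' deposited table. Several of these events lay near the limit of 20 reads per library: Dusp13 (26 and 20.3), Tnnt1 (23.5), Pard3 (22, deposited FDR 0.0139), Slc25a15 (20.3) and Thoc1 (22.8, deposited FDR 0.0389). Depth was higher for Mast2 (34.7), Htra2 (45.7), Scaf11 (52.7), Popdc3 (148) and Mief2 (271), per the authors' deposited table. The share of called introns higher in the knockout was 60% (45 of 75, exact binomial interval 48 to 71.1). Called introns had a median length of 259 bp against 234 bp for all tested introns (permutation p = 0.514, two-sided).

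CASH called far fewer events, 28 of 60273 at the deposited FDR of 0.05, in 26 genes. Inclusion was higher in the control for 18 and in the knockout column for 9 in the authors' deposited table, and 11 were cassette exons, 5 retained introns, 4 alternative ends and none mutually exclusive exons. Its knockout column held the reads of 2 of the 3 knockout libraries. Inclusion of the Mybpc1 exon went from 62.1% (95% exact binomial interval 61.2 to 62.9) to 80.3% (79.5 to 81) and of the Itga7 exon from 61.4% (57.6 to 65.1) to 38.5% (34 to 43.3), per the authors' deposited table. A short stretch of Klhl33 listed as a retained intron (chromosome 14, 51126320 to 51126350) had 590 reads for inclusion and 0 for exclusion in the control. That count of 0 allows up to 0.508% exclusion. Inclusion of this stretch was 38.7% (31.3 to 46.5) in the knockout column, per the authors' deposited table. Whether so short a gap is a spliced intron was not tested. A 3' splice site of Hjv, or hemojuvelin, a regulator of iron balance, went from 58.2% (56.9 to 59.5) to 88.8% (87.6 to 90) in the authors' deposited table. A cassette exon of Fermt2, or kindlin-2, went from 55.5% (51.1 to 59.9) to 80.9% (77.4 to 84.1), and the Jph1 alternative end from 76.9% (74 to 79.6) to 54.6% (49.8 to 59.3), per the authors' deposited table. Klhl33 and Fermt2 lie 3.75 and 9.18 Mb from Acin1. These intervals and floors cover counting error only, since reads added over libraries hide the spread between animals and amplified reads are not independent molecules.

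Genes called by CASH were mostly genes called by rMATS. Of 25 genes with a CASH call that rMATS also tested, 17 had an rMATS call, against 1.87 by chance (Fisher's exact test, two-sided, odds ratio 27.2, p = 3.5e-14), from the same libraries and so not independent. Genes that changed in expression and genes that changed in splicing shared 78 names among 6394 tested for both, against 64.7 by chance (odds ratio 1.27, Fisher's exact p = 0.0701), a difference that did not pass. Jph1 fell in expression and had a CASH call.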

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

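The alternatives without the trend, with a trimmed-mean scaling, without genes near Acin1 and with the authors' p-values were chosen after the data were seen; the others were planned. Of the settings tried for the count of genes past the threshold, 13 stayed within 1.5 times of 1645. It was 357 with a log2 change of at least 1 and 792 without the trend, and leaving out 1 library gave 477 to 1520, with fewer libraries in each fit. For Acin1 the direction held in all 17 settings, and the call was lost in 5: without the trend (log2 change -0.32, adjusted p = 0.082) and without 4 single libraries (range over all left-out libraries -0.36 to -0.29); the cause was not tested. Camera passed 14 lists at the preset correlation of 0.01 and 0 with an estimated correlation, which puts the same question with another correlation between members. The estimates ran from 0.0179 for cholesterol and fatty acid synthesis to 0.838 for tendon markers, with 0.496 for neonatal and regenerating fibre genes. Fry, which asks other questions than camera, passed 0 lists for direction and 23 for change in either direction. With looser or stricter limits the rMATS counts were 664 skipped exons, 66 alternative 5' sites and 92 alternative 3' sites at the authors' FDR alone, 56 and 23 alternative 5' sites at means of 5 and 20 reads, and 34 mutually exclusive exons at a difference of 0.1, by construction. The share of retained introns higher in the knockout passed an exact binomial test against an even split with more events, 61% at FDR 0.1 (exact p = 0.021) and 52.6% over all tested introns (exact p = 0.0167). All introns come from the same 6 libraries, so these 2 p-values do not measure the spread between libraries. The called introns were not tested against the 52.6% of all tested introns. No named gene that was called changed sign, the other genes and the events not being followed one by one, but the balance of 839 higher and 806 lower genes turned to 696 and 824 without knockout replicate 5 and to 309 and 389 without replicate 7. Medians of lists that had not passed also changed sign: matrix genes from -0.19 to 0.14 without knockout replicate 5, and immediate early genes from 0.18 to -0.21 and macrophage markers from 0.07 to -0.29 without replicate 8. Of single named genes and events, 2457 settings kept their side of the threshold, 341 lost the call and 51 gained it; of single lists, 253 kept it, 43 lost it and 10 gained it. Of 97 named genes called, Acin1 apart, limma without the trend lost 56, robust limma 14, limma-voom 11 and scaling by library size 8. No paired analysis was possible because the control replicates 1, 2 and 3 and the knockout replicates 5, 7 and 8 share no number. Not run were count-model tools, no low-count filter, a sex covariate, and splicing tests per library. On simulated reads at this depth and number of libraries 30% of 1.5-fold changes were recovered. Only 200 genes were changed there, fewer than the 1645 called here, so the share recovered in these data may differ.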

Other observations

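The tests around Acin1 on genes and on CASH events, those on the regenerating fibre genes and on non-fibre markers, and the count of splits were chosen after the results were seen; the test of rMATS events around Acin1 was written before. Of 28 glycolysis and glycogen genes 3 fell by limma in both adjustments (camera adjusted p = 0.569): Hk2, or hexokinase 2, from 10400 ± 4202 to 4023 ± 345 scaled reads (SD, n = 3 each, log2 change -1.30, adjusted p = 0.0126), Pfkfb1 (-0.65) and Phka1 (-0.59). Of these Hk2 was called without each library; Pfkfb1 was lost without control replicate 1 or 3 (adjusted p = 0.052 and 0.0503) and Phka1 without control replicate 1, 2 or 3 or knockout replicate 7 (0.0842, 0.092, 0.0676 and 0.0657). Of 29 fatty acid genes, Eci1 (0.54) and Etfa (0.52) rose and Ppargc1a, the coactivator of mitochondrial biogenesis, changed by -0.75, with the same counts over the list alone (camera adjusted p = 0.21, 0.00633 without knockout replicate 8, where 5 rose). Etfa was lost without control replicate 1, 2 or 3 or knockout replicate 7 (0.0835, 0.0753, 0.0814 and 0.0804), and Ppargc1a without knockout replicate 7 (0.0573). Of 33 nuclear oxidative phosphorylation genes 1 rose, Cox8b (0.36, lost with limma-voom at adjusted p = 0.0508), and 0 over the list alone, while the list passed (camera adjusted p = 0.00825, adjusted p = 0.932 with an estimated correlation) except without control replicate 1 (0.105) or knockout replicate 5 (0.157). None of its members rose without control replicate 1, 2 or 3 or knockout replicate 5 or 7, and 3 rose without knockout replicate 8. None of 13 mitochondrially encoded messengers was called by limma, in either adjustment, and the smallest unadjusted p was 0.217. Of 25 cholesterol and fatty acid synthesis genes 3 rose and 1 fell in both adjustments (camera adjusted p = 0.807), with Pnpla3, a lipid droplet hydrolase, from 28.6 ± 1.83 to 122 ± 15.5 (1.94, adjusted p = 0.0011). In that list 1 gene rose without control replicate 1, 2 or 3 or knockout replicate 7 and 2 without knockout replicate 5 or 8, and 0 fell without control replicate 1 or 2 or knockout replicate 5 or 8 and 2 without control replicate 3. Of 27 atrophy genes Cdkn1a rose and Fbxo31, Ulk1 and Mstn, or myostatin (-1.17), fell, 2 and 5 over the list alone (camera adjusted p = 0.812); none of the falls was called without control replicate 1, 2 or 3 or knockout replicate 7, and robust limma lost Mstn and Ulk1 (adjusted p = 0.0769 and 0.0527). None of the atrophy genes rose without control replicate 1, 2 or 3, and 3 rose without knockout replicate 5; 2 fell without knockout replicate 8. Of 21 integrated stress genes 1 rose and 2 fell in both adjustments (0.846); 2 rose without control replicate 3 and 0 without any other library, and 1 fell without control replicate 1 or 3 or knockout replicate 7. Of 19 clock genes 3 fell, Tef (-0.50), Nr1d2 and Dbp, with 6 lower and 1 higher over the list alone (camera adjusted p = 0.021, adjusted p = 0.775 with an estimated correlation, 0.0703 without knockout replicate 7); Dbp was lost with robust limma (0.0591), and 1 clock gene fell without control replicate 1, 2 or 3 and 2 without knockout replicate 7.

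Of the other cell-type lists, 0 of 20 macrophage, 0 of 2 lymphocyte and neutrophil and 0 of 4 skin markers were called by limma in either adjustment; the smallest unadjusted p in each was 0.00622, 0.523 and 0.107. The macrophage list did not pass (camera adjusted p = 0.61, 0.0197 without knockout replicate 5, where 1 rose). Of 13 adipocyte markers 1 rose in both adjustments, Car3, a carbonic anhydrase also abundant in muscle fibres, from 43420 ± 6745 to 104500 ± 35290 scaled reads (SD, n = 3 each, log2 change 1.23, limma adjusted p = 0.0144, lost without control replicate 2 or 3 at 0.0511 and 0.0623), while the other 12 had lower means (camera adjusted p = 0.0894, 0.0157 without knockout replicate 5, where 2 fell). Of 13 tendon markers 1 fell in both adjustments, Kera (-1.49; list 0.516, 0.024 without control replicate 2), and of 15 satellite cell markers 1 in both, Notch3 (list 0.224), with 0 called without control replicate 1, 2 or 3 or knockout replicate 5 or 8. None of 31 matrix genes and none of 25 immediate early genes was called by limma in either adjustment, with smallest unadjusted p of 0.059 and 0.0157; the matrix list passed without control replicate 2 (0.0281) or knockout replicate 8 (0.0136), and the immediate early list without knockout replicate 7 (0.000154), where 1 rose; 1 also rose without control replicate 3, and 1 fell without knockout replicate 8. Reads of Y-linked genes were found in all 6 libraries. Uty rose from 268 ± 9.77 to 448 ± 23 (0.73, adjusted p = 0.00432), Eif2s3y changed from 1035 ± 165 to 495 ± 66.9 (-1.05, adjusted p = 0.00507) and Kdm5d by -0.45 (lost without any 1 of control replicates 1, 2 and 3 or knockout replicates 7 and 8, adjusted p from 0.0696 to 0.114), the same 3 over the list alone, and Ddx3y was not called (-0.13, adjusted p = 0.303).

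Calls were dense around Acin1 on chromosome 14. Within 1 Mb of it, 11 of 35 genes were called, 31.4%, against 4.15 in expression-matched sets (permutation p = 0.0008). Of 108 genes 1 to 10 Mb from it, 23 were called, 21.3%, against 11.5% of 11934 genes elsewhere. Expression-matched sets of that size held a mean of 12.7 called genes (permutation p = 0.0028). The interval from 50 to 55 Mb, which holds genes at both distances, had the highest share of 238 intervals (16 of 37 genes). CASH calls in the authors' deposited table stood in 4 of 218 genes 1 to 10 Mb from Acin1, Fermt2, Ktn1 and Klhl33 among them. Elsewhere they stood in 21 of 18842 genes (odds ratio 16.8, Fisher's exact p = 0.000174). Events of rMATS gave an odds ratio of 1.78 (10 of 200 events, Fisher's exact p = 0.0858, 95% interval 0.834 to 3.36). Counted by gene, as for CASH, 6 of 59 genes had an rMATS call, 10.2% against 7.21% elsewhere (odds ratio 1.46, Fisher's exact p = 0.319). An effect of the altered gene on its direct neighbours alone is argued against by the 23 calls beyond 1 Mb, over the 19 that bounds matched sets. A share of such an effect in the 11 calls within 1 Mb is left open. A stretch of donor-strain chromosome carried along with the floxed alleles may account for the excess, in expression and in CASH events. The test of rMATS events missed the threshold fixed beforehand, but its interval reaches well above 1. Reading a missed threshold as absence was wrong, so that test decides nothing, and no strain is labelled. Calls outside this region, such as those of the Y-linked Uty and Eif2s3y, were not tested for a difference of strain between the groups.

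The neonatal and regenerating fibre list was highest in knockout replicate 8. That library alone is argued against, since the list passed without it (camera adjusted p = 6.41e-06 at a preset correlation) with 9 members called. With all libraries the list did not pass at an estimated correlation (adjusted p = 0.775), so this rests on the preset correlation and on the members. RNA of slow muscle in the knockout samples cannot be told apart from a change within fibres: the slow light chain Myl3 went the other way (log2 change -2.42), but the 240 scaled reads that Myh7 gained are fewer than the SD of Myl3 in the control libraries (669). Formation of new fibres after loss of Acin1 may underlie the rise; this is a hypothesis that staining of sections for embryonic myosin and central nuclei would test.

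Endothelial, smooth muscle and Schwann markers were lower while macrophage markers were not. A lower share of all non-fibre RNA in the knockout samples may explain this, or fewer such cells or less of their RNA. Macrophage markers lay 0.459 above the other 46 markers in median log2 change (permutation p = 6e-05). That permutation moved markers between lists, so its p-values do not measure the spread between libraries. Over all libraries the difference goes against an even loss. Without knockout replicate 8 it was 0.0842 (permutation p = 0.257), so the explanations cannot be told apart.

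Of the 10 ways to split the 6 libraries into groups of 3, the real one gave 1645 genes and the highest of the others 0, so that 1 split, the real one, reached that count; 10 splits are too few for a share under 0.05.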
